A study of Mus musculus with 2 samples.

How the data were processed

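The series holds 2 single-cell RNA libraries from the preoptic area of C57BL/6J mice aged 9 to 10 weeks, made with Act-seq and 10x Genomics chemistry, per the labels. One library came from mice after 6 h of sleep deprivation (SD), and the other from mice given 2 h of recovery sleep after 6 h of sleep deprivation (SD+RS). Each library pooled males and females, and the number of mice in each pool is not given in the sources used here. The groups were taken from the treatment label of each sample.

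The deposited matrices hold UMI counts per gene and cell, written by Cell Ranger 3.0.2, per the file headers. The genome build was mm10, and Seurat 4.0.4 is also named, per the submitters' processing notes. The matrices list 31054 genes, 1 of them a YFP sequence, and 31011 of the gene identifiers were found in the GENCODE vM21 annotation used here for coordinates. The barcodes had already been called as cells, since the lowest barcode had 504 UMIs in the SD library and 501 in the SD+RS library. The authors also deposited tables of marker genes for clusters of each library and of both together, and a table of genes compared between 2 sets of cells within their cluster i2. These deposited tables give a p-value and an adjusted p-value computed over cells, per the file headers. They give each gene's average difference as a log whose base is left open, per the file headers, which are those of Seurat versions older than the one named. The values are closer to a natural log: for Gnrh1 the authors' deposited table gives 6.43, and the counts gave 6.22 as a natural log and 8.98 as log2. They give the share of cells with the gene as a fraction for the cells of the cluster and for the other cells, per the file headers. The authors' cluster of each cell was not used here, so all cluster names were rebuilt, and the deposited tables were set only beside the rebuilt clusters.

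Cells were kept with at least 500 genes and under 20% mitochondrial UMIs, which left 9875 of 10262 barcodes in the SD library and 7709 of 8106 in the SD+RS library. Doublets were called in each library from simulated pairs of its own cells, 2 simulated doublets per cell and an expected rate of 6%, with the score threshold placed between the modes of the simulated scores, at 0.12 and 0.17. The caller marked 708 cells (7.17%) of the SD library and 334 (4.33%) of the SD+RS library, and it marked 68.4% and 57.8% of the simulated doublets. Marked cells were removed, leaving 9167 and 7375 cells. UMIs were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 40 principal components, and a graph of 20 neighbours was split with the Leiden method at resolution 1.0, both libraries together with no correction between them. Genes of the activity, stress, clock and cold-inducible lists given below were left out of the clustering. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and YFP were left out too. Neurons were clustered again on their own in the same way at resolution 1.5.

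Clusters were named from markers fixed before the data were examined, as were the groups, the gene lists, the rule for named genes and the alternatives listed below except those named as added. A name needed at least 3 markers of the class, each in at least 20% of the cluster's cells, and the class was that with the highest marker score. A cluster stayed unnamed where another class reached 0.75 of that score, where its leading genes were markers of another class, or where it had a median UMI count under its own library's (or, for neurons, under that of all neurons) divided by 3 with no marker of its class among its top 10 genes. The marker scoring and these thresholds were set after the data had been seen, and they left 2 clusters unnamed. The first had neuron markers at low depth and held 6.04% of SD cells and 0.963% of SD+RS cells. The second had markers of endothelial and mural cells together and held 1.70% and 1.83%. Classes were described with at least 100 cells in each library, which 7 classes had, and neuron clusters with at least 50, which 34 of 42 had.

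Values are sums of UMIs over the cells of a class or cluster, scaled to all UMIs of that class or cluster and given as CPM. With 1 library per group no test of the groups was possible, so no p-value was computed. Each value has an exact Poisson interval, each share an exact Clopper-Pearson interval and each ratio an exact conditional binomial interval, all at 95% and all covering counting error only. Log2 ratios are SD+RS over SD throughout. Over the genes with at least 50 UMIs in both libraries, the median log2 ratio of a class lay between −0.02 in neurons and 0.08 in endothelial cells. Where a library had 0 UMIs of a gene, the limit set by 3 counts was used. Shares of cells with a Fos UMI were compared after thinning each cell to 2000 UMIs, with shallower cells left out, by 1 shared draw for all cells, and the share expected over all draws was also computed. Cells were called by sex where they had Xist UMIs and no UMI of Ddx3y, Uty, Kdm5d or Eif2s3y, or the reverse.

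The 21 gene lists were core immediate early genes (14 genes), other early genes (23), late activity genes (16), heat shock (14), unfolded protein response (19), glucocorticoid response (16), clock (20), cold-inducible RNA binding (3), cholesterol synthesis (19), glycolysis (15), mitochondrial-encoded genes (13), cytosolic ribosome (83), myelin (10), cell cycle (15), astrocyte metabolism and transport (13), homeostatic microglia (9), activated microglia (12), interferon response (10), GABA and glutamate synapse (16), adenosine (9) and neuropeptides (24). Some lists share members: Per1 is in the late activity, glucocorticoid and clock lists, and Vgf and Scg2 are in the late activity and neuropeptide lists. A member was measured in a class with at least 20 UMIs over both libraries. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Members were counted as higher or lower where they differed by more than 1.5 times. The named genes were every measured core immediate early gene in neurons, the 10 highest and 10 lowest ratios in neurons, the 3 highest and 3 lowest in every other described class, up to 4 members of each list with the largest ratio and an interval that excluded no difference, the 3 neuron clusters with the highest and lowest core sum, and the 4 highest and 4 lowest of 48 neuron markers. Candidates had at least 50 UMIs in the class in a library, at least 20 CPM, and at least 0.1 of the level of the class with most. Mitochondrial, ribosomal, haemoglobin, predicted and sex-linked genes were not candidates. A few genes that the rule names are not reported here. For the neuron cluster with the highest core sum the rule for neurons was also applied to that cluster alone, a choice made after its values were seen.

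The alternatives were a stricter cell filter (1000 genes, 10%), doublets kept, scaling within each library, a doubled resolution (2.0), median-of-ratios scaling, scaling without mitochondrial and ribosomal UMIs, the mean over cells, cells of each sex alone, thinning to 1000 or 4000 UMIs, at least 2 UMIs of a marker, list members with at least 100 UMIs or at least 1 with a prior of 0.5, named genes with at least 200 UMIs or with no minimum against other classes, the core sum without its most abundant member or as a geometric mean, and neuron resolutions of 0.75 and 3.0. Those added later are named in the closing section. The ratio, its interval and the list percentile were tested on simulated counts over 12966 genes. These were Poisson counts drawn from the pooled profile of 2000 random cells of each library, with no spread between cells. The test therefore covers counting error only, and the filter, doublet calls, clustering, thinning and sex calls were not part of it. Genes changed by 0.25, 0.5, 2 and 4 times came back with median log2 ratios of −1.98, −1.00, 0.99 and 2.00. The 95% intervals covered the true ratio for 95.5% of genes, and 5.0% of unchanged lists of 15 genes fell in the lowest or highest 2.5% of the random lists. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.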

Results

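The preoptic area is a region at the front of the hypothalamus that holds neurons which promote sleep and others that control body temperature, mating and parenting. The study set out to find which of its neurons are active in the rebound sleep that follows sleep loss, from marker genes of cell clusters and from immediate early genes, which neurons transcribe within minutes of firing. Act-seq dissociates tissue with a blocker of transcription present, so that activity genes are less induced by the handling itself. The SD library held 10262 barcodes and 132191585 UMIs, with a median of 7534.5 UMIs and 2948 genes per barcode. The SD+RS library held 8106 barcodes and 123500649 UMIs, with medians of 14774 and 4529. After filtering and removal of doublets, 9167 cells of the SD library and 7375 of the SD+RS library were described. Each group was 1 library without replicates, so every interval below covers counting error only, and no difference between the libraries could be set against a spread between mice.

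Both libraries held the neurons, glia and vascular cells of the preoptic area, and neurons made up the largest class in each. Neurons were 41.6% of SD cells (95% interval 40.6 to 42.6, 3816 cells) and 58.1% of SD+RS cells (57.0 to 59.2, 4285 cells). Astrocytes, which take up glutamate and potassium around synapses, were 22.4% (21.6 to 23.3) and 17.1% (16.3 to 18.0). Oligodendrocytes, which form myelin, were 14.8% and 11.1%, and endothelial cells 4.996% and 3.81%. Oligodendrocyte precursors (2.89% and 2.36%), microglia (2.36% and 2.24%) and mural cells of the vessel wall (2.32% and 1.67%) were rarer. Neurons had a median of 21848 UMIs in the SD library and 21204 in the SD+RS library. A cluster of shallow cells with neuron markers was left unnamed and held 6.04% of SD cells and 0.963% of SD+RS cells. The sexes were mixed differently: cells with Xist UMIs only were 49.6% of cells with a sex call in the SD library and 78.9% in the SD+RS library, and among neurons 38.9% (37.3 to 40.6) and 77.4% (76.1 to 78.6).

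**Figure D1:**
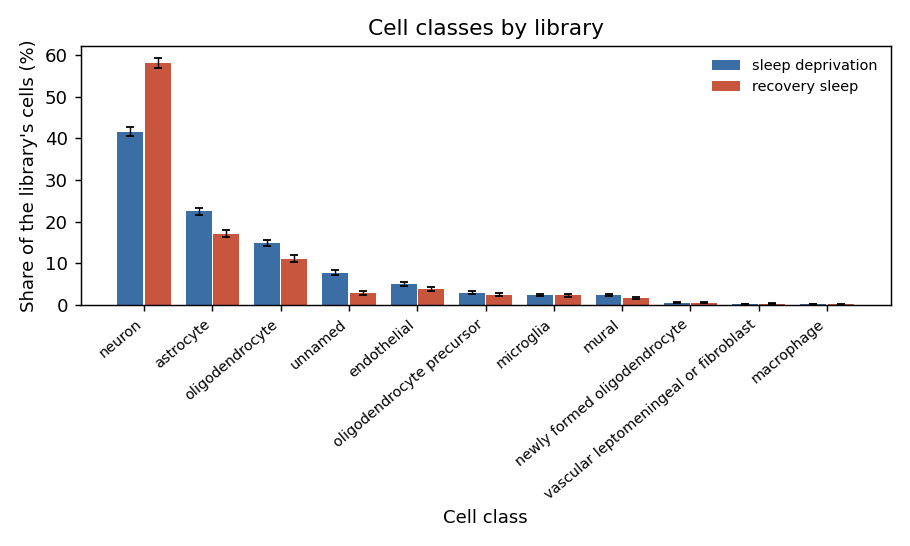
Bars give each class as a percentage of its library's cells in the SD and SD+RS libraries, with 95% Clopper-Pearson intervals as error bars. Neurons were 41.6% and 58.1%, and astrocytes 22.4% and 17.1%.

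Taken as 1 class, neurons had nearly equal levels of the core immediate early genes after sleep deprivation and after recovery sleep. The 14 genes summed to 219.6 CPM (217 to 223), which is their UMIs scaled to all UMIs of the class, in the SD library and 239 (236 to 242) in the SD+RS library, a log2 ratio of 0.12 (0.09 to 0.15). Fos, whose protein forms the AP-1 transcription factor with Jun proteins, was at 47.9 and 51.2 CPM, a log2 ratio of 0.10 (0.04 to 0.16). Fos lies on chromosome 12 from 85473890 to 85477273 in mm10. The members differed in direction. Fosb had a log2 ratio of 0.55 (0.40 to 0.69), Btg2 0.41, Dusp1 0.38, Npas4 0.34, Arc 0.32 and Junb 0.25. Egr1, a zinc finger transcription factor, was lower at −0.34, from 46.2 to 36.5 CPM, and Nr4a3 was lower at −0.25 (−0.47 to −0.03). Egr3 was at 0.00, Egr4 at 0.06, Nr4a1 at −0.03 and Ier2 at −0.02, with intervals that included 0. Egr2 had 11 and 23 UMIs, a log2 ratio of 0.92 (−0.17 to 2.10). The median of the list in neurons was 0.17, in the highest 2.5% of random lists, while that of the other early genes was −0.18, in the lowest 2.5%. In cells with Xist UMIs only, neuronal Fos had a log2 ratio of −0.11 (−0.19 to −0.02) and Nr4a3 of 0.44, and in cells with Y-linked UMIs only neuronal Fos had 0.39 (0.28 to 0.49) and Nr4a3 −1.06. Egr3 had 0.66 in the former and −0.66 in the latter, where Egr4 had −0.83.

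A Fos UMI was found in 28.1% of neurons of the SD library and 33.6% of the SD+RS library before thinning. With every cell thinned to 2000 UMIs the shares were 7.52% (6.70 to 8.40, 38 cells left out) and 8.28% (7.47 to 9.14, 8 left out), and over all possible draws the expected shares were 7.13% and 7.85%. Astrocytes, at median depths of 3426 and 3144 UMIs, had a Fos UMI in 3.13% and 3.08% of thinned cells, with 170 and 92 left out, and in 5.30% and 4.28% without thinning. Endothelial cells had one in 92.2% and 92.9% of thinned cells.

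The largest difference among the neuron clusters was in a small GABAergic cluster that expressed galanin, the precursor of neurokinin B, and the CART peptide. Its leading genes were Tac2, Amigo2, Gal, Cbln2, Cartpt and Gpr139. This Gal Tac2 Cartpt cluster held 93 neurons of the SD library and 76 of the SD+RS library, at median depths of 32546 and 32373 UMIs. Its core immediate early genes summed to 51.7 CPM (43.7 to 60.7, 147 UMIs) after sleep deprivation and 791.7 (757 to 828, 1924 UMIs) after recovery sleep. That is a 15.3-fold higher level (12.95 to 18.2), a log2 ratio of 3.94 (3.70 to 4.19). Among the 34 described neuron clusters it had the lowest level in the SD library and ranked 2 from the highest in the SD+RS library, behind a cluster led by Gng8, C1ql1 and Hopx at 766.5 and 1176 CPM. The cluster was 2.44% and 1.77% of neurons, and it held 0.757% of all neuronal core UMIs in the SD library and 8.25% in the SD+RS library. Without it the core sum of neurons had a log2 ratio of −0.00 and neuronal Fos one of −0.08. The clustering used none of the genes of the activity lists, though other genes given below as higher in the cluster, such as Tgfb2, Rrad and Rem2, were not barred from it. Cells with Xist UMIs only numbered 45 in the SD library and 69 in the SD+RS library, and cells with Y-linked UMIs only 43 and 6.

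**Figure D2:**
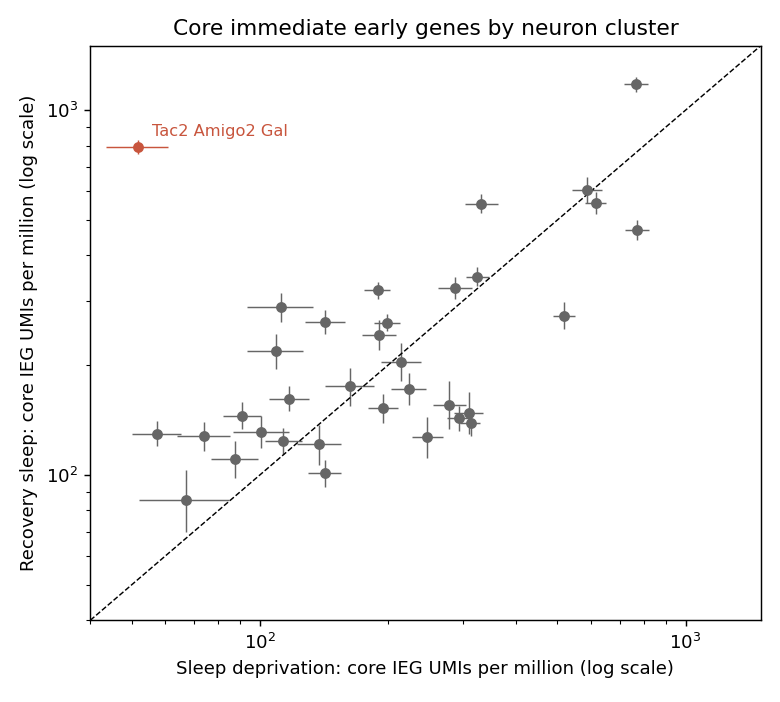
Each point is 1 of the 34 described neuron clusters, with core immediate early gene levels in CPM for the SD library on the x axis and for the SD+RS library on the y axis, both logarithmic, 95% counting intervals as bars and a dashed line at equal levels. The cluster led by Tac2, Amigo2 and Gal, in red, lies at 51.7 and 791.7.

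Fos itself was near the floor in these cells after sleep deprivation and abundant after recovery sleep. It was at 2.81 CPM (1.21 to 5.54, 8 UMIs) in the SD library and 222 (203 to 241, 539 UMIs) in the SD+RS library, a log2 ratio of 6.30 (5.31 to 7.52). As a mean over cells, the ratio of Fos in the Gal Tac2 Cartpt neuron cluster was 5.51, and in cells with Y-linked UMIs only it was 8.41 (5.88 to 13.7, 1 UMI in the SD library). A Fos UMI was found in 8 of 93 cells (8.60%, 3.79 to 16.2) and 70 of 76 cells (92.1%, 83.6 to 97.0). After thinning to 2000 UMIs it was found in 0 of 92 cells, which allows up to 3.26% of cells with a UMI at that depth, with 1 cell left out, and in 31 of 76 (40.8%, 29.6 to 52.7). Over all draws the expected shares were 0.924% and 32.4%, below and above the 3.18% and 2.66% expected in astrocytes. The 11 core genes with enough UMIs were all more than 1.5 times higher, with a median log2 ratio of 4.06. The orphan nuclear receptor genes Nr4a3 and Nr4a1 had log2 ratios of 6.06 (4.17 to 9.12, 2 UMIs in the SD library) and 4.61, and Egr3 had 4.98 (3.06 to 8.06, also 2 UMIs). Egr4 (4.16), Fosb (4.06), Egr1 (3.80, from 10.5 to 146.5 CPM) and Junb (3.56, from 10.9 to 129) followed, then Npas4 (2.99), Arc (2.49) and Dusp1 (2.36). Ier2 at 0.23 and Btg2 at 0.81 had intervals that included 0, and Egr2 had no UMI in either library. Egr1 lies on chromosome 18 from 34859823 to 34864984 and Junb on chromosome 8 from 84974484 to 84978718.

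**Figure D3:**
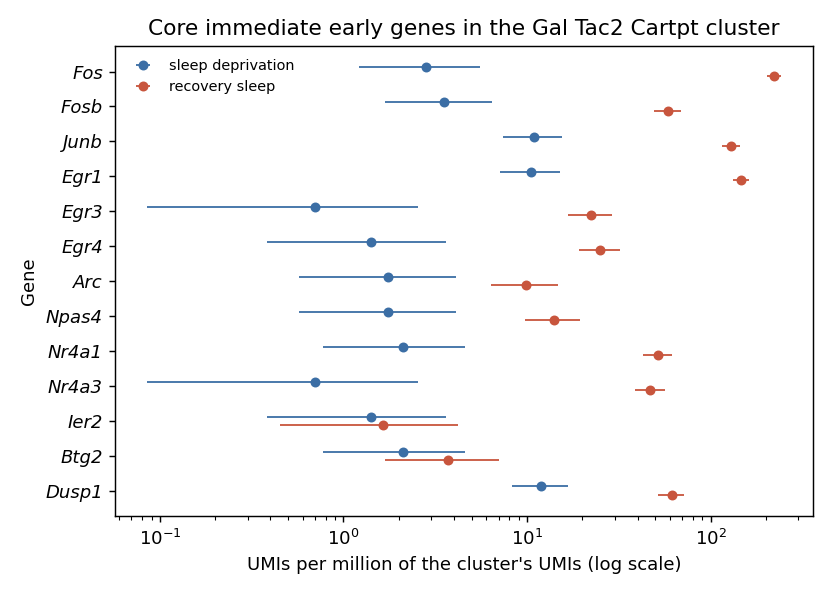
Points give CPM on a logarithmic axis for 13 core immediate early genes in the cluster led by Tac2, Amigo2 and Gal, for the SD library (93 cells) and the SD+RS library (76 cells), with 95% Poisson intervals. Fos was at 2.81 and 222, and Egr2 is not plotted because it had no UMI.

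Other activity lists were also higher in this cluster. The other early genes had a median log2 ratio of 1.38, with 8 of 14 measured members more than 1.5 times higher and 1 lower, and the late activity genes one of 0.93, with 7 of 10 higher. Both medians lay in the highest 2.5% of random lists. Among genes that pass the minimum levels of the naming rule, and outside the core set, Dusp14 and Fosl2 had log2 ratios of 3.49 (2.72 to 4.36) and 3.35 (2.52 to 4.30), and they were followed by Tgfb2 (2.53), the transcriptional repressor Nfil3 (2.31), and the small GTPases Rrad (2.13) and Rem2 (2.08). Under the same rule the lowest ratios were smaller in size: Pnrc2 −1.67 (−2.31 to −1.08), Ormdl1 −1.45, Med20 −1.38, Pik3ip1 −1.20, Parm1 −1.19, Elk1 −1.18, Nhlrc1 and Pdrg1 −1.15 each, and Lrch3 and Bid −1.14 each. Heat shock genes in the cluster had a median of −0.06 and unfolded protein genes of −0.02, neither in the outer 2.5% of random lists. The clock list had a median of −0.17 with 5 members higher and 4 lower. Nts was found in 93.5% of its cells and 35.7% of other neurons, at means of 11.4 and 5.4 UMIs per 10000. Rxfp1, the relaxin receptor, was found in 19.5% and 4.03% (0.174 and 0.0393 UMIs per 10000), and Esr1, the estrogen receptor, in 2.96% and 26.7% (0.0125 and 0.259). Gal lies on chromosome 19 from 3409915 to 3414544, Tac2 on chromosome 10 from 127724478 to 127731768, Cartpt on chromosome 13 from 99898489 to 99901091, Cbln2 on chromosome 18 from 86711110 to 86718283 and Amigo2 on chromosome 15 from 97244125 to 97247287.

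The authors' deposited tables hold a cluster with the same leading genes. In the authors' deposited table of both libraries, their cluster i2 had Tac2 in 95.8% of its cells against 22.1% of others, at a natural-log difference of 2.56, and differences of 2.16 for Gal, 1.90 for Cartpt, 1.65 for Cbln2, 1.52 for Serpine2 and 1.51 for Amigo2. The authors' deposited table of cluster i2 compared 2 sets of its cells that it does not name, and gave Fos in 8.9% and 92.1% of them with an adjusted p-value over cells of 4.86e-23. Junb (22.2% and 85.5%) and Egr1 (22.2% and 82.9%) differed in the same sense in that authors' deposited table. Of its 30 genes, 22 had the lower share in the first set in the authors' deposited table, and all 22 had the lower share in the SD library here. The other 8 had the higher share in both. The authors' deposited tables were made from these same libraries. The largest differences of a share were 4.03 percentage points (first set and SD) and 3.97 (second set and SD+RS). This match was therefore bound to come out and adds no support, and the p-value takes cells rather than mice as units. In the authors' deposited table of the SD library alone, cluster 22 with Tac2 in 96.8% of cells had Fos in 8.6% of cells against 27.3% of others, and in the authors' deposited table of the SD+RS library, cluster 23 with Tac2 in 98.4% had Fos in 96.9% against 32.9%.

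Other neuron clusters had smaller ratios, in both directions. Of the 34 described clusters, 16 had a higher core sum in the SD+RS library and 11 a lower one with intervals that excluded no difference, and outside the cluster above the median log2 ratio was 0.13 (quartiles −0.38 to 0.62). The next highest was a cluster led by Sox14, Fam159b and Npffr1, at 112 and 289 CPM (1.36, 1.08 to 1.66), with 1.96 in cells with Xist UMIs only. A GABAergic cluster led by Nts, Grp and Vip had 57.3 and 129.8 (1.18, 0.96 to 1.41). Lower after recovery sleep were a cluster with Crh and Foxp2 among its leading genes, at 313 and 139 (−1.17, −1.31 to −1.04), 1 led by Six3, Pmaip1 and Arhgap36, at 309.6 and 148 (−1.07), and 1 led by Gbx1, Sema3c and Satb1, at 293 and 143 (−1.04). Several clusters carried markers of regions next to the preoptic area. At least 3 of 6 striatal markers were found in 5 clusters, though 1 of these was glutamatergic and free RNA was not ruled out, and suprachiasmatic markers (Vip, Prok2 and Rgs16) in a cluster of 108 SD and 176 SD+RS neurons. The supraoptic or paraventricular markers Oxt, Sim1 and Otp were found in another 5 clusters, though 49.3% of all neurons outside the Gal Tac2 Cartpt cluster had an Oxt UMI.

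Neurons of the preoptic area are often defined by 1 marker gene, and 44 of the 48 markers were found in enough neurons. Neurons were grouped by at least 1 UMI of the marker, which free RNA can also give: outside the cluster above, 39.6% of neurons had a Gal UMI and 49.3% an Oxt UMI. The ratio of the core sum was highest in neurons with an Rxfp1 UMI, at 117 and 373 CPM (1.67, 1.54 to 1.81, 185 and 168 neurons). That ratio was 1.21 without the Tac2, Amigo2 and Gal cluster and 2.28 with at least 2 Rxfp1 UMIs. Cplx3 neurons had 218 and 506 (1.21, 1.03 to 1.40; 1.90 with at least 2 UMIs), Moxd1 neurons 221 and 379.7 (0.78) and neurons with Th, the enzyme of dopamine synthesis, 265 and 437 (0.72, but 0.37 without the cluster). Neurons with a Gal UMI had 187.6 and 263 (0.49, 0.45 to 0.53), and 0.23 without the cluster. Without it, Tac2 neurons had 0.18 in place of 0.68, Vip neurons −0.30 in place of 0.70, Cartpt neurons −0.16 in place of 0.26 and Nts neurons −0.08 in place of 0.25. The lowest were Lhx8 neurons, at 229 and 178 (−0.37, −0.43 to −0.31), then Tacr3 (−0.31, but 0.03 in cells with Xist UMIs only), Pvalb (−0.28, but 0.19 in cells with Y-linked UMIs only) and Hcrtr2 (−0.25) neurons. The Rxfp1 gene lies on chromosome 3 from 79641611 to 79737880.

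Over all genes, the 10 highest ratios of neurons included Srsf5 and Cirbp of the cold-inducible RNA-binding list, and the 10 lowest included co-chaperone genes. Srsf5, a splicing factor, was at 273 and 414 CPM (0.60, 0.58 to 0.62), and the cold-inducible Cirbp at 203 and 282 (0.47, 0.45 to 0.50). Vip had the highest ratio, from 29.7 to 56.6 (0.93, 0.864 to 0.999), but −1.40 in cells with Y-linked UMIs only. It was among the leading genes of 2 clusters, with 108 and 136 neurons in the SD library and 176 and 184 in the SD+RS library, and Prok2 among those of 2 others, with 85 and 53 neurons in the SD library and 141 and 97 in the SD+RS library. Tipin (0.88), C1ql2 (0.62, and 1.78 in cells with Y-linked UMIs only, and the leading gene of a cluster of 80 SD and 139 SD+RS neurons), Esr1 (0.58, from 21.3 to 31.8), Armcx5 (0.55), Prok2 (0.48), Yif1a (0.44) and Mrnip (0.39) completed the 10 highest. Among the lowest were the co-chaperones Dnajb1, from 92.97 to 51.1 (−0.86, −0.91 to −0.81), Ahsa2 (−0.59) and Chordc1 (−0.55). Cys1 (−0.90), Ccdc85b (−0.89), Banp (−0.85), P4ha1 (−0.66), Gstp1 (−0.64), Grp (−0.61, and −1.95 in cells with Y-linked UMIs only) and the progesterone receptor Pgr (−0.57, from 41.4 to 27.9) made up the rest. Vip lies on chromosome 10 from 5639218 to 5647617, Cirbp on chromosome 10 from 80165985 to 80172786 and Dnajb1 on chromosome 8 from 83608193 to 83612653. Neurons also carried fewer transcripts of other classes in the SD+RS library: the myelin list had a median of −0.55 and the astrocyte list one of −0.41 in neurons.

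Stress response genes were lower after recovery sleep in every described class. Heat shock genes had medians from −1.01 in mural cells to −0.21 in neurons, glucocorticoid response genes from −1.06 in astrocytes to −0.21 in neurons, and unfolded protein genes from −0.51 in oligodendrocyte precursors to −0.13 in neurons. Every one of these medians lay in the lowest 2.5% of random lists. The synapse list of neuronal genes also had low medians outside neurons, at −1.10 in astrocytes, −1.75 in oligodendrocytes and −1.66 in mural cells, while in oligodendrocyte precursors its −0.17 was not in the lowest 2.5%. Mitochondrial-encoded genes were in the lowest 2.5% in 6 classes, and the shallow cluster held more of the SD cells (6.04%) than of the SD+RS cells (0.963%). More than 1.5 times lower were 11 of 14 heat shock genes in astrocytes, 13 of 14 in mural cells, 12 of 14 in oligodendrocytes and 3 of 14 in neurons. The inducible chaperones Hspa1a and Hspa1b had log2 ratios of −3.00 and −2.54 in astrocytes and −2.52 and −2.41 in oligodendrocytes, and Hspa1b had −1.36 in neurons. Of glucocorticoid response genes, 10 of 16 in astrocytes, 13 of 15 in oligodendrocytes and 6 of 16 in neurons were lower. They included Fkbp5, a co-chaperone of the glucocorticoid receptor, at −2.26 in astrocytes, and the kinase Sgk1 at −2.01 in astrocytes and −0.59 in neurons. Of unfolded protein genes, 7 of 19 in astrocytes, 6 of 19 in oligodendrocytes and 7 of 19 in oligodendrocyte precursors were more than 1.5 times lower. Only 3 of 19 were in microglia, 1 of 19 in endothelial cells and 0 of 19 in neurons. Xbp1 had −0.87 in astrocytes, −0.91 in oligodendrocytes and −1.35 in oligodendrocyte precursors, where Hspa5 had −1.29 and Manf −1.39.

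The cold-inducible RNA-binding list of Cirbp, Rbm3 and Srsf5 was higher in all 7 classes, with medians from 0.16 in astrocytes to 1.40 in microglia, and in the highest 2.5% of random lists in 6 of them. Cirbp had log2 ratios of 0.99 in astrocytes, 1.36 in oligodendrocytes, 1.40 in microglia and 1.76 in endothelial cells. In cells with Y-linked UMIs only, Cirbp in endothelial cells was at 2.496. Clock genes differed in both directions, with medians from −0.20 in oligodendrocytes to 0.24 in mural cells (−0.49 there in cells with Y-linked UMIs only). The clock list lay in the lowest 2.5% of random lists in neurons, at −0.18, and in the highest 2.5% in mural cells, and in no other class was it in either. Dbp, an output gene of the clock, was higher in astrocytes (1.01), endothelial cells (1.63) and mural cells (0.58), and Arntl lower in endothelial cells (−2.42). Per2 (−0.36), Nfil3 (−0.37) and Npas2 (−0.41) were lower in neurons, and Usp2 (0.33, 0.16 to 0.50) was higher. The hour of day at which each library was collected is not given in the sources used here.

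**Figure D4:**
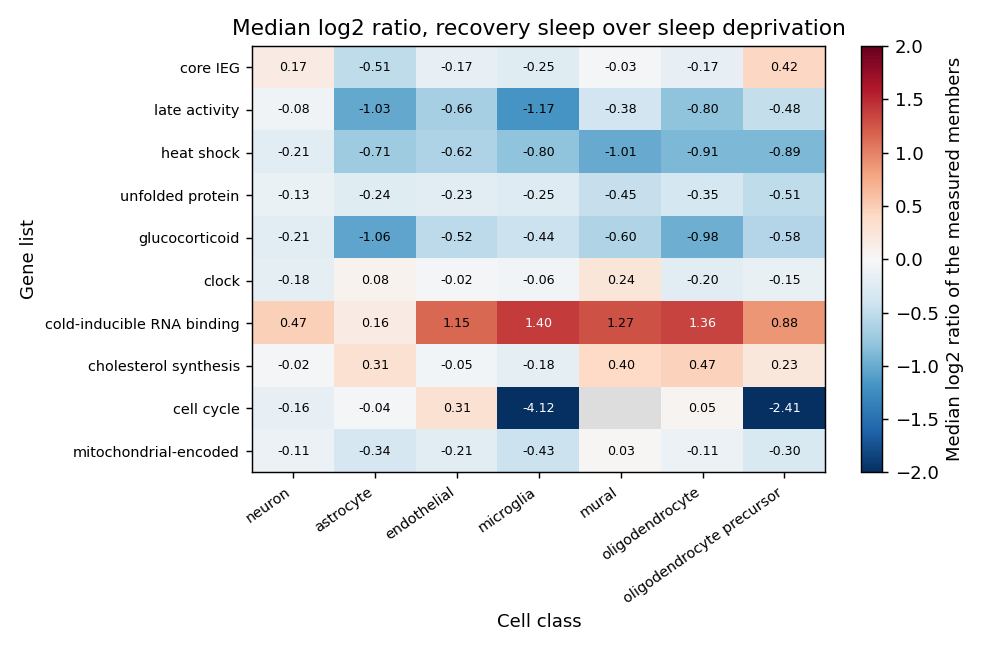
The heat map gives the median log2 ratio (SD+RS over SD) of 10 gene lists in the 7 described classes, with each value printed, a colour scale from −2 to 2 and grey where a list was not described. Heat shock, unfolded protein and glucocorticoid lists lie below 0 in all 7 classes, and the cold-inducible list above 0.

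Core immediate early genes were most abundant in vessels, at similar levels in both libraries, and among glia they were lower after recovery sleep in astrocytes and higher in oligodendrocyte precursors. Endothelial cells had 16535 CPM in the SD library and 15221 in the SD+RS library (−0.12, −0.14 to −0.09), and mural cells 7695 and 7656 (−0.01). Microglia had 912 and 935 (0.04, −0.10 to 0.17). Astrocytes were lower, at 80.2 and 60.3 (−0.41, −0.63 to −0.19, 580 and 248 UMIs), and at −1.36 with doublets kept. Neuronal transcripts were also lower in astrocytes (synapse list −1.10), and whether carried-over neuronal RNA accounts for the lower core sum was not tested. Oligodendrocytes were at 185 and 155 (−0.25), but at 0.47 in cells with Y-linked UMIs only and −0.59 in those with Xist UMIs only. Oligodendrocyte precursors were higher, at 468.5 and 681 (0.54, 0.36 to 0.72), and their Fos was at 83.0 and 196 CPM (1.24, 0.86 to 1.62). A Fos UMI was found in 11.6% of thinned precursors of the SD library (6 left out) and 27.5% of the SD+RS library (3 left out), and in 22.6% and 40.2% without thinning. As list medians, the core set ran from −0.51 in astrocytes (−1.58 with doublets kept) to 0.42 in precursors (−0.19 there in cells with Y-linked UMIs only), other early genes from −0.33 in endothelial cells to 0.21 in microglia, and late activity genes from −1.17 in microglia (−0.14 with doublets kept) to −0.08 in neurons. The synapse list, which holds neuronal genes, had −1.74 beside −1.17 for late activity in microglia, −1.10 beside −1.03 in astrocytes, −1.07 beside −0.66 in endothelial cells and −1.75 beside −0.80 in oligodendrocytes. In mural cells the synapse list (−1.66) lay in the lowest 2.5% and the late activity list (−0.38) did not, and in oligodendrocyte precursors the late activity list (−0.48) did and the synapse list (−0.17) did not. The late activity genes with the lowest ratios in astrocytes were Nrn1 (−1.72), Syt4 (−1.67), Bdnf (−1.51) and Vgf (−1.26), which neurons express.

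Astrocytes and endothelial cells held single genes with low ratios. In astrocytes the Notch target Hes5 had 95.9 and 417 CPM (2.12, 1.99 to 2.25), followed by Tmem86a (1.47) and Kif21b (1.44). At the doubled resolution most astrocytes of the 2 libraries lay in different clusters, 1 with 1745 SD and 131 SD+RS cells, and 1 led by Hes5 with 102 and 1057. Arl4d was at 46.2 and 1.22 (−5.25, −6.88 to −4.01), Bambi at −3.06 (−3.68 to −2.50) and Tcim at −2.65 (−1.96 in cells with Y-linked UMIs only). In endothelial cells Tgfb2 (1.73) and Dbp were highest after Cirbp. Lrg1 had −5.08 (−8.14 to −3.19), Fkbp5 −4.25 (−7.32 to −2.34) and the potassium channel gene Kcna5 −3.91 (−6.99 to −1.99), each with 2 UMIs in the SD+RS library. In cells with Xist UMIs only Lrg1 in endothelial cells was at −1.45, Fkbp5 in endothelial cells at −2.95 and Kcna5 in endothelial cells at −3.26. As a mean over cells they were at −4.39, −5.18 and −5.01. In mural cells Otud1 was at 1.53 (0.67 in cells with Y-linked UMIs only) and Rbm3 at 1.27, and the lipase inhibitor Angptl4 at −4.31 (−7.39 to −2.40, 2 UMIs in the SD+RS library, with Angptl4 in mural cells at −5.26 under the stricter filter). Syt4 (−2.54) and Ndrg4 (−2.03) were low in mural cells too, but at −0.14 and 0.21 with doublets kept. Both are transcripts of neurons, and in mural cells the synapse list had a median of −1.66 with 7 of 7 measured members lower and the neuropeptide list one of −0.65. Hes5 lies on chromosome 4 from 154960923 to 154962371 and Fkbp5 on chromosome 17 from 28399094 to 28517527.

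Oligodendrocytes were higher in the linker histone gene Hist1h1c (1.68, 1.51 to 1.86) and in Rbm3 (1.57), and lower in Fkbp5 (−2.40, −2.93 to −1.92), Zbtb16 (−2.25) and the NF-kB inhibitor Nfkbia (−2.01). With scaling within each library, 1 oligodendrocyte cluster held 1094 SD and 246 SD+RS cells, and another, led by Opalin, 1 and 446. In cells with Y-linked UMIs only, Fkbp5 in oligodendrocyte cells was at −3.76 and Zbtb16 in oligodendrocyte cells at −3.38. Microglia were higher in Mthfd2 (2.03, 1.32 to 2.79), the chemokine Ccl4 (1.65) and Il6st (1.60), while in cells with Xist or Y-linked UMIs only Mthfd2 was at 1.18 and 3.22 and Ccl4 in microglia cells at 1.06 and 2.996. They were lower in Cd74 (−1.71, −2.38 to −1.08), Pnmal2 (−1.62) and Rcan1 (−1.60). Cd74 was at −1.07 under the stricter filter, Pnmal2 at −0.06 with doublets kept, and in cells with Y-linked UMIs only Cd74 was at −0.70 and Rcan1 at −0.33, against −2.62 and −2.60 in cells with Xist UMIs only. Oligodendrocyte precursors were higher in Cirbp (1.47), Cklf (1.21) and Ache (1.13, and 1.80 in cells with Y-linked UMIs only), and lower in the mitotic genes Cdk1 (−3.39, −5.30 to −1.97), Ube2c (−3.17) and Cdc20 (−3.14), which were at −2.42 for Ube2c and −2.18 for Cdc20 as a mean over cells. Their UMIs were 70 and 4 for Cdk1, 105 and 7 for Ube2c and 59 and 4 for Cdc20. The number of precursors that carried them is not given here, and the intervals take no account of UMIs that share a cell.

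Transcripts of neurons in other classes were lower in the SD+RS library, though the neuropeptide list in microglia (−0.72) reversed with doublets kept. The GABA and glutamate synapse list had medians from −1.75 in oligodendrocytes to −0.05 in neurons, and the neuropeptide list from −1.06 in oligodendrocyte precursors (−0.39 for members with at least 100 UMIs) to 0.08 in neurons, where Avp had 0.36, Gal −0.30 (1026 to 831 CPM) and Cck −0.44. Mitochondrial-encoded genes had medians from −0.43 in microglia to 0.03 in mural cells and lay in the lowest 2.5% of random lists in 6 classes. The cytosolic ribosome list ran from −0.30 in astrocytes to 0.07 in microglia. Glycolysis genes ran from −0.23 in microglia (0.017 with doublets kept) to 0.07 in neurons, where they lay in the highest 2.5%, and the adenosine list from −0.01 in mural cells to 0.33 in endothelial cells, where 3 members were measured and a prior of 0.5 gave −0.16.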

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

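The tests of handling, of the loss of cytoplasmic RNA, of doublets, of free RNA and of a single mouse were chosen only after the result they bear on had been seen. The other tests were recorded as written down before, but they are worded for patterns found in these data, and the pick by marker genes uses leading genes of the cluster.

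Neuron clusters differed in opposite directions between the same 2 libraries: the core immediate early genes had a log2 ratio of 3.94 in the cluster led by Tac2, Amigo2 and Gal and −1.17 in a cluster with Crh and Foxp2 among its leading genes, a difference that was not tested. The sex mix of the pools is argued against, because the ratio was 3.90 (3.57 to 4.25) in cells with Xist UMIs only and 4.32 in the few cells with Y-linked UMIs only. To see whether activity genes pulled cells into the cluster, neurons were picked without clustering, from at least 3 UMIs of Gal and Tac2 and at least 1 of Cbln2 and Amigo2. These 147 SD and 121 SD+RS neurons had 3.35 (3.17 to 3.53). This value cannot decide the question, because the picking genes are leading genes of the cluster and 156 of the picked neurons lie in it. The picked neurons outside the cluster, 62 and 50 cells, had 1.94 (1.66 to 2.23). A higher core sum was thus not limited to the cells grouped by the clustering, though it was smaller outside. A uniform effect of handling or dissociation on a whole library is argued against by the other described clusters, whose median was 0.13 (quartiles −0.38 to 0.62). An effect that differs between neuron types cannot be decided by this median. Heat shock, unfolded protein and glucocorticoid genes were also lower in the SD+RS library in all 7 described classes. A response of these neurons to recovery sleep stays open as a hypothesis, since each group was 1 library, and the mice, their handling and any difference in the hour of collection go with the groups.

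A cluster of shallow cells with neuron markers, left unnamed and outside the main comparisons, held 6.04% of the SD library's cells (554 cells, against 71 in the SD+RS library). These cells may be damaged neurons of many types: each was assigned to the neuron cluster with the most similar profile, and the most frequent of these took 13.9% of them and the next 4.64%, with 41 clusters taking at least 1 cell, although the most frequent was led by Oxt and Avp and free RNA of these genes may have added to it. A loss of cytoplasmic RNA also had the values it needs, with 5 nuclear non-coding RNAs taking 2.37 times the share of UMIs that they took in SD neurons (4.58% and 1.93%; 2.35 times without Miat, the first leading gene of the cluster, but 1.63 times for Malat1 alone), and ribosomal protein genes 2.56% against 8.04%. Doublets are argued against, since in a clustering with doublets kept the caller marked 0.0% of the 548 SD cells of the matching cluster and 7.17% of all SD cells. No biological explanation was tested.

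A YFP transcript, which the labels of wild-type mice do not mention, stood out as a signal outside the genes compared, with 4463 UMIs in 310 cells of the SD library (3.38%, 3.02 to 3.77) and 229 UMIs in 29 cells of the SD+RS library (0.393%). In the SD library 5.24% of neurons and 1.80% of astrocytes had it, at median depths of 21848 and 3426 UMIs. Free RNA or misassigned reads are argued against as the whole source, because 93.7% of the SD library's YFP UMIs lay in cells with at least 5, and 92 of those 98 cells were neurons. A single mouse is argued against only as far as the sex calls hold, with Xist UMIs only in 77 of 90 such cells (85.6%, 76.6 to 92.1) and Y-linked UMIs only in 13. Another 7 of the 98 cells had both kinds of UMIs, and the error rate of the sex calls was not measured. No biological explanation was tested. By number, most of the strong SD cells in any cluster were in those led by Sostdc1, Amigo2 and Gal (16 of 173 SD cells), by Iapp, Calcr and Brs3 (15 of 85) and by C1ql3, Sox3 and YFP itself (15 of 85). The first of these was the larger cluster and had the lower share.

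Neuronal Fos stood out because it had opposite directions in cells of the 2 sexes, with a log2 ratio of −0.11 in cells with Xist UMIs only and 0.39 in cells with Y-linked UMIs only, a difference that was not tested.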

How the results depend on the processing

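The added alternatives were chosen only after the data had been seen: leaving out the cluster led by Tac2, Amigo2 and Gal, counting the shallow cluster as neurons, leaving out a shallow neuron cluster of 92 SD and 8 SD+RS cells, Fos in the cluster under the alternatives, and the naming rule applied to the cluster alone. No paired analysis was possible because each group had 1 library. Intervals of list medians came from a bootstrap over members.

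In the cluster led by Tac2, Amigo2 and Gal the core immediate early gene (IEG) sum kept its direction under every alternative run, with log2 ratios from 3.72 to 4.32, and Fos in the Gal Tac2 Cartpt neuron cluster from 5.51 to 8.41. The core sum of oligodendrocyte precursors lay between 0.43 and 0.60. Clusters at neuron resolutions of 0.75 and 3.0 held 98.8% and all of the cluster's cells. Of the values that answer a comparison, 85 stayed within their main interval, 25 lay outside it without reversing, and 4 reversed, which counts only values whose main interval excluded 0. For single genes, markers and lists these were 2053, 253 and 16. Of the 10 highest and 10 lowest genes of neurons, all were shared with a minimum of 200 UMIs, and 9 and 6 with no minimum against other classes. The minimum of 200 UMIs kept 0 of the 3 highest and 0 of the 3 lowest in microglia, mural cells and precursors, 2 and 0 in endothelial cells, 1 and 3 in astrocytes and 2 and 3 in oligodendrocytes. No minimum against other classes kept 3 and 0 in microglia, 0 and 1 in mural cells, 2 and 3 in precursors, 3 and 3 in endothelial cells, 2 and 2 in astrocytes and 3 and 1 in oligodendrocytes.

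The values below are log2 ratios unless given as percentages, and the cause was not tested for any of them. In cells with Xist UMIs only, neuronal Fos was −0.11 (reversed) and the core sum 0.029 in neurons, −0.089 in endothelial cells, 0.27 in microglia, −0.14 in mural cells and −0.59 in oligodendrocytes. There Nr4a3 in neurons (0.44), Tacr3 neurons (0.027) and the list cytosolic ribosome in endothelial cells, median log2 ratio 0.0049, and the myelin list in precursors (0.50) reversed, and neurons were 36.0% and 59.9% of SD and SD+RS cells. In cells with Y-linked UMIs only, the core sum was 0.47 in oligodendrocytes (reversed), 0.25 in neurons, 0.077 in mural cells and 4.32 in the cluster, and Fos was 0.39 in neurons and 8.41 in the cluster. There Vip (−1.40), Pvalb neurons (0.19), the core list in precursors (−0.19) and the ribosome list in mural cells (−0.18) reversed, and the neuron share of cells, SD (percent) and then SD+RS (percent), was 55.7 and 65.6. With doublets kept, the core sum was −1.36 in astrocytes and 0.085 in neurons, and Ndrg4 in mural cells (0.21), glycolysis (0.017) and neuropeptides (0.62) in microglia and myelin in precursors (0.35) reversed. As a mean over cells, the core sum was −0.020 in endothelial cells, 0.089 in mural cells and 0.092 in neurons, and the ribosome list in endothelial cells reversed (0.0059). With median-of-ratios scaling, the core sum was −0.20 in endothelial and −0.080 in mural cells, and the ribosome list in mural cells reversed (−0.023). The neuronal core sum was 0.073 without its most abundant member and 0.19 as a geometric mean. Without the cluster the neuronal core IEG sum was −0.0030 and neuronal Fos −0.077, both reversed. With the shallow cluster counted as neurons these were 0.12 and 0.11, and without the shallow neuron cluster 0.12 and 0.095, all within their main intervals. With a prior of 0.5 the adenosine list in endothelial cells reversed (−0.16). Under the stricter filter the myelin list in mural cells reversed (0.31), and neurons were 45.6% and 59.8%.

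Depth sets the share of neurons with a Fos UMI, which was 3.84% and 4.44% at 1000 UMIs per cell and 11.8% and 13.5% at 4000. It also limits genes with 2 UMIs in a library, the 93 and 76 cells of the cluster, and lists with few measured members.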

Other observations

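No explanation was tested for the values in this part, and genes of the cluster led by Tac2, Amigo2 and Gal were chosen only after its values had been seen.

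Genes of cholesterol synthesis, which supplies myelin and other membranes, were higher after recovery sleep in oligodendrocytes, with a median log2 ratio of 0.47 and 6 of 19 members more than 1.5 times higher. Among them were Mvk (1.09), Hsd17b7 (0.997) and Dhcr7 (0.89). Astrocytes had a median of 0.31, with Insig1 at 0.66 and Fdft1 at 0.53, mural cells one of 0.40, and the lowest was −0.18 in microglia. The list lay in the highest 2.5% of random lists in 4 classes. The myelin list had a median of 0.09 in oligodendrocytes, where Opalin was at 453 and 843 CPM (0.90, 0.85 to 0.95) and Mag, Mog and Cnp at 0.32, 0.28 and 0.27. In the other classes it was lower, down to −0.95 in endothelial cells (−1.66 with doublets kept), and in precursors its −0.86 turned to 0.35 with doublets kept. It also reversed in precursors in cells with Xist UMIs only, and in mural cells (−0.85) under the stricter filter. Oligodendrocyte precursors were lower in cell cycle genes, with a median of −2.41 (−3.17 in cells with Y-linked UMIs only) and 9 of 14 members more than 1.5 times lower. Ccnb1 and Mki67 were both at −3.23, Mki67 with 47 and 3 UMIs (−5.56 to −1.59). Microglia had a cell cycle median of −4.12 over 7 members, of which 2 had no UMI in a library, −2.34 with these at their limits and −0.42 as a mean over cells. Endothelial cells had the highest median, 0.31.

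Homeostatic microglia genes had a median of 0.20 in microglia, with P2ry12 at 0.40, Sall1 at 0.37 and Gpr34 at 0.31, and of −0.53 in neurons. Activated microglia genes had a median of 0.38 in microglia, in the highest 2.5% of random lists, with 3 of 8 members more than 1.5 times higher and 1 lower. These were the chemokines Ccl4 (1.65), Ccl2 (1.03) and Ccl3 (0.71) and the lipid carrier Apoe (−1.72). In other classes that list ran from −1.11 in astrocytes (−0.14 with a prior of 0.5) to 0.81 in mural cells (−0.56 with doublets kept). Interferon response genes ran from −0.32 in mural cells to 0.97 in oligodendrocyte precursors, where 3 were measured, and had 0.76 in astrocytes, with 5 of 6 higher and Ifit1 at 1.48 and Ifit3 at 0.85. The list of astrocyte metabolism and transport had a median of 0.03 in astrocytes (−0.03 with doublets kept), with Kcnj10 at 0.31, Glul at −0.29 and Gys1 at −0.63. It ran from −0.41 in neurons to 0.08 in mural cells (−0.59 with doublets kept).

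In the cluster led by Tac2, Amigo2 and Gal, the clock genes Usp2 (2.89, 1.64 to 4.42), Per2 (2.55, 1.26 to 4.10) and Per1 (1.57, 1.10 to 2.06) were higher in the SD+RS library, while Per2 had −0.36 over all neurons and the clock list as a whole had a median of −0.17 in the cluster, with 5 members higher and 4 lower. Per1 is also a member of the late activity list, so its ratio is not a separate result of the clock list. Cdkn1a (2.51), Dusp4 (2.76), Crem (1.27), Cited2 (1.71) and Fam46a (1.37) were also higher, and so was Penk (1.81, 0.74 to 3.01), the enkephalin precursor, at 3.51 and 12.3 CPM. Penk was found in only 4.14% of the cluster's cells and in 23.9% of other neurons (0.0648 and 1.73 UMIs per 10000). Its ratio thus rests on few cells, and free RNA was not ruled out.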
